A study of Mus musculus with 3 samples.

How the data were processed

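RNA sequencing was analysed for 3 libraries of differentiated C2C12 myotubes, 1 each from control DMEM, S2-013 conditioned media, and S2-013 conditioned media with 50 µM resveratrol. Per the labels' protocols, cells were grown with 10% fetal bovine serum, RNA was extracted with TRIzol and RNeasy columns, and libraries were made with an Illumina TruSeq version 2 kit. Samples were placed in groups by their treatment labels. The sources used here do not give the serum content of the control DMEM or of the medium that was conditioned, nor the solvent of resveratrol, and a culture with resveratrol in control medium was not analysed here. The comparisons were conditioned media against control, resveratrol in conditioned media against conditioned media, and resveratrol in conditioned media against control.

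The submitters' processing notes name the mm10 genome build, FastQC 0.69, Trim Galore 0.4.3.1, TopHat2 2.1.0, Bowtie, Cufflinks 2.2.1.0 and Cuffdiff 2.2.1.3. The annotation, strand setting and scaling between libraries are not given in the sources used here. The deposited table has the layout of Cuffdiff's gene-level output, with 24401 loci in each of 3 comparisons. Its FPKM values were computed by the authors as fragments per length of transcript and per number of mapped fragments, and they are the same for a library in each comparison. The log2 fold change in the deposited table is the authors' log2 ratio of FPKM without a pseudocount, and is infinite where a library is at 0. Cuffdiff's test statistic, a score, and its p-values and q-values are in the deposited table as the authors' values, with a smallest p of 5e-05 and q-values of the called loci from 0.000148 to 0.04996. A Benjamini-Hochberg adjustment over the tested loci used here did not return the q-values, so how they were adjusted is unknown and they were taken as deposited. With 1 library per condition the test has no spread between replicate cultures of a condition to draw on, and a call says that these libraries differ. How Cuffdiff estimated its spread is not given in the sources used here.

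Depth is unknown. The lowest values were searched for steps of whole reads by looking for a repeated ratio between libraries among loci that the authors did not test, and the most frequent ratio was held by at most 4 of 4007 loci. FPKM summed to 3384770 in control, 2953950 in conditioned media and 2956880 with resveratrol, and 83.0%, 79.3% and 78.4% of these sums lay in loci of 200 bases or less, most of them without a gene symbol. Rescaling FPKM to TPM therefore follows these short loci, and shifts log2 ratios of both conditioned media libraries over control by 0.20 and 0.19 before the pseudocount. Medians of 12 lists turned sign under that shift, 2 of lists that stood apart, where this is said beside them, and 10 of lists inside the random range, where it is not.

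Differences were computed as log2((FPKM + 1)/(FPKM + 1)) on the deposited values. A locus counted as higher or lower by the size rule when its absolute log2 ratio was 1 or more, its mean FPKM over the 3 groups was 1 or more, and the authors' table marked it as tested or not tested for low data. This left 11858 loci, of which 360 had no gene symbol, 258 had several symbols, and 11211 different single symbols remained. Loci are Cufflinks bundles, and 5611 share their position with another locus. Starts in the deposited table count from 0, since the start plus 1 equalled the RefSeq start of the same symbol in 10489 of 22351 loci and the start itself in 617, and were converted to 1-based positions. Genes that hold a small RNA gene of 200 bases or less on their strand were found in GENCODE M21, the same build, for 11141 of 11211 symbols (99.4%), of which 993 hold one. Where a symbol had several loci, the one with the highest mean was used for lists.

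The 37 gene lists, with 862 genes of which 741 were measured, and the rule for named genes were fixed before the data were examined. For each list with 3 or more measured genes, the percentile of its median log2 ratio was found among 10000 random lists of the same size, matched on 20 bins of mean expression. Medians below percentile 2.5 or above 97.5 are described as standing apart, which describes these libraries and is not a test of the conditions. The text names, for each comparison, the 10 highest and the 10 lowest genes with 1 symbol that passed the size rule and are called in the authors' table, leaving out predicted models and small RNA genes, then up to 4 genes per list by absolute log2 ratio, and 15 genes fixed by name. Some genes that this rule names are not reported here. Where the size of both comparisons was set side by side, unchanged libraries were simulated 1000 times with each library's variance solved from the standard errors that the authors' fold changes and test statistics imply.

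The size rule and the list percentiles were tested on simulated data for the conditioned media over control comparison, over 11211 genes. Of 200 genes changed by 4-fold, 200 were recovered, 0 of 11011 unchanged genes passed the rule, 8 of 200 unchanged lists fell outside the central 95%, and a list shifted by 0.3 was placed at percentile 100. These figures rest on an assumed noise of 0.15 on the log2 scale, and the changed genes were drawn from better expressed genes only. They do not give the recovery of low genes. With the errors that the authors' test implies, a mean of 83.3 of 10640 simulated unchanged loci passed the rule in the same comparison. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a mean FPKM of 5 or more, centring on the median, rescaling to TPM, tested loci only, a q-value of 0.01 or less, and the authors' calls joined with the filter or the size rule. Loci with 1 symbol only, genes without a small RNA gene, and TPM for lists and named genes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.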

Results

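RNA was sequenced from C2C12 myotubes, muscle fibres formed in culture from a mouse myoblast line. The myotubes had been differentiated for 72 hours in DMEM with 2% horse serum and 1 µg/ml insulin, and were then kept for 24 hours in 1 of 3 media. The control culture received DMEM. The conditioned media culture received medium that S2-013 cells, a human pancreatic cancer line, had conditioned for 24 hours. The resveratrol culture received the same kind of conditioned medium with 50 µM resveratrol, a plant polyphenol. Each group held 1 library, so no difference described here has a replicate check, and no SD or p-value of its own could be given. The values are the authors' FPKM for 24401 loci, of which 11666 reached 1 FPKM in control, 12004 in conditioned media and 11609 with resveratrol. Read totals are unknown, since FPKM carries no count, and the precision of single values could not be computed from it. FPKM values below are given in the order control, conditioned media, conditioned media with resveratrol, and log2 ratios are on the log2(FPKM + 1) scale, which understates the change of low genes.

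The first comparison asks how myotubes in pancreatic cancer cell conditioned medium differed from myotubes in DMEM. Genes of inflammation and of cytokine signalling were higher. Among 27 measured NF-κB and cytokine genes, 7 were higher by the size rule (an absolute log2 ratio of 1 or more) and 0 were lower, with a median log2 ratio of 0.52 that lay above all 10000 random lists matched on expression. They included Nos2, the inducible nitric oxide synthase, at 15.7, 94.2 and 49.5 FPKM (log2 ratio 2.51), Cxcl1, a neutrophil chemokine, at 26.8, 83.4 and 162 FPKM (log2 ratio 1.60), and Icam1, a leukocyte adhesion molecule, at 0.131, 4.10 and 0.631 FPKM. Lcn2, an acute phase protein gene, stood at 0.0778, 2.69 and 6.47 FPKM, and the authors' deposited table does not call it. Of 16 JAK-STAT3 genes, 3 were higher by the size rule and 15 had ratios above 0, with a median of 0.63. Serpina3n, an acute phase serine protease inhibitor, was listed at 0 in control and at 13.4 and 14.9 FPKM in the conditioned media libraries. Pim1, a kinase gene, stood at 6.02, 14.7 and 32.7 FPKM, and Cebpd, a transcription factor gene, at 9.72, 22.8 and 41.0 FPKM. Il6 was at 5.72, 11.5 and 18.6 FPKM, Stat3 at 43.2, 59.5 and 66.8 FPKM and Socs3, a feedback inhibitor of cytokine receptors, at 12.7, 22.7 and 68.8 FPKM, with log2 ratios of 0.90, 0.45 and 0.80 for conditioned media over control. The interferon list lay on the other side. Its 27 genes had a median of -0.23 (percentile 0.12), with Oas2 at 84.2, 42.1 and 22.8 FPKM and Ifi44 at 186, 102 and 63.2 FPKM, while Psmb9, an immunoproteasome subunit, was higher at 6.35, 18.8 and 19.2 FPKM.

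Of the 10 single-symbol genes highest in conditioned media that the authors' deposited table calls, Prg4, which encodes the joint lubricant lubricin, had the largest ratio among those above 0 FPKM in control. It lies at chromosome 1, positions 150361311 to 150466230 of mm10, shares that span with other loci, and stood at 7.12, 103 and 118 FPKM (log2 ratio 3.68). Next were Nos2 (chromosome 11, 78920685 to 78960221), the alarmin Il33 at 6.07, 38.2 and 12.2 FPKM (chromosome 19, 29925114 to 29960715), Selenbp1 at 1.57, 12.3 and 4.52 FPKM, Cd209c at 5.68, 30.5 and 14.0 FPKM, Icam1, the matrix protein gene Tgfbi at 1.98, 12.2 and 5.50 FPKM and Mgst2, a microsomal glutathione transferase, at 1.22, 8.79 and 14.5 FPKM. Wfdc17 was listed at 0 in control and at 3.98 and 3.62 FPKM in the conditioned media libraries. At the lower end stood Fam65a (chromosome 8, 105566695 to 105622218) at 282, 21.7 and 17.8 FPKM and the RNA helicase gene Ddx39b at 399.7, 108 and 299 FPKM. Both genes hold a small RNA gene on their own strand, whose reads the value may include. They were followed by Egr3, an early growth response factor, at 16.8, 3.95 and 3.32 FPKM, Myl9, a myosin light chain of smooth muscle and non-muscle cells, at 80.1, 26.5 and 35.1 FPKM, Actg2, smooth muscle gamma actin, at 92.3, 31.3 and 24.1 FPKM, Srm, spermidine synthase, at 51.0, 17.1 and 13.2 FPKM, the lysophospholipid transporter Mfsd2a at 7.78, 2.07 and 1.32 FPKM, Cnn1, calponin, at 4.25, 0.940 and 0.847 FPKM, Daam2 at 11.0, 3.46 and 4.65 FPKM and Dynap at 41.7, 15.0 and 4.88 FPKM. Cnn1 lies in a span given to 14 loci, so its value is uncertain.

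Muscle genes were on the lower side in conditioned media. Of 16 myogenic regulators, 15 had ratios below 0, with a median of -0.24 (percentile 1.06). The 1 that passed the size rule, Id2 at 32.4, 15.3 and 17.5 FPKM, is an inhibitor of myogenic factors. Id3, also an inhibitor, was the only one above 0, at 14.0, 22.4 and 48.7 FPKM. Myod1, the myoblast determination factor, stood at 48.2, 28.2 and 51.7 FPKM (log2 ratio -0.75) and Myog, myogenin, at 384, 313 and 596 FPKM (log2 ratio -0.29). Of 22 excitation-contraction genes, 20 had ratios below 0 and 0 passed the size rule, with a median of -0.25 (percentile 0.27). Cav3, the muscle caveolin, was at 36.9, 20.4 and 41.0 FPKM and Jph2, a junctional membrane protein, at 53.9, 31.5 and 65.7 FPKM. The 36 sarcomere genes had a median of -0.12 (percentile 2.16), which turned to 0.075 after FPKM were rescaled to TPM, with 24 ratios below 0. Ttn, titin, was at 19.97, 10.1 and 7.34 FPKM, Xirp1 at 14.5, 7.16 and 16.0 FPKM and Mybph, a myosin binding protein, at 299, 156 and 533 FPKM. Among 15 genes of the ubiquitin atrophy programme, 13 had ratios above 0 and 0 passed the size rule, and the median of 0.14 lay at percentile 95.7, inside the central 95% of random lists, but above it (percentile 97.7) at a mean FPKM of 5 or more. Trim63 and Fbxo32, the muscle ubiquitin ligases also known as MuRF1 and atrogin-1, stood at 10.6, 21.2 and 17.5 FPKM and 11.6, 18.8 and 19.7 FPKM (log2 ratios 0.93 and 0.66), and the transcription factor gene Foxo3 at 17.4, 31.6 and 27.4 FPKM. The 31 proteasome genes had a median of -0.21 (percentile 0.09) with 28 ratios below 0. The 20 autophagy and lysosome genes had a median of 0.26, above all random lists, with Bnip3 at 184, 364 and 291 FPKM and Sqstm1, the autophagy receptor p62, at 207, 276 and 400.3 FPKM. Mstn, myostatin, was listed at 0 in control and below 0.1 FPKM in the other libraries.

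Genes of glucose use and of the hypoxia response were higher in conditioned media. The glycolysis list had a median of 0.29, with 20 of 25 ratios above 0, and the hypoxia list one of 0.31, with 19 of 24 above 0. Both lay above all random lists, and 0 members passed the size rule. Pfkp, a phosphofructokinase, stood at 38.1, 74.5 and 28.4 FPKM, the lactate transporter Slc16a1 at 28.2, 48.8 and 83.6 FPKM, and Ndrg1, a hypoxia-induced gene, at 152, 303 and 151 FPKM. Ldha, lactate dehydrogenase A, at 829, 822 and 666 FPKM, Slc2a1, the glucose transporter GLUT1, at 101, 94.9 and 136 FPKM, and Hk2, hexokinase 2, at 27.8, 34.3 and 40.5 FPKM, had log2 ratios of -0.013, -0.082 and 0.29. Oxidative phosphorylation genes (median -0.024, percentile 38.8), TCA cycle and fatty acid genes (median -0.024), and genes of mitochondrial biogenesis and the sirtuins (median -0.037) lay inside the random range. Angptl4, a lipoprotein lipase inhibitor, was at 94.4, 36.0 and 73.0 FPKM. Sirt1 was at 8.72, 7.48 and 18.4 FPKM and Ppargc1a, which encodes PGC-1α, at 0.642, 1.20 and 0.347 FPKM. The 31 cholesterol and lipid genes had a median of -0.15 (percentile 2.42), which turned to 0.045 after rescaling to TPM.

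Cell cycle genes split by phase. All 34 G2/M genes had ratios above 0 in conditioned media, with a median of 0.45 and 0 past the size rule, whereas 31 of 33 S phase genes had ratios below 0, with a median of -0.53 and 3 past the rule. The first lay above and the second below all random lists. Cdc6 and Mcm5, which license replication origins, stood at 5.53, 1.66 and 3.19 FPKM and 17.3, 7.70 and 7.20 FPKM, and Cdca3, a mitotic gene, at 15.3, 25.05 and 4.29 FPKM. Replication-dependent histone genes were higher, with 5 of 10 past the size rule and a median of 0.95. Hist1h1c, a linker histone, was at 86.1, 305 and 191 FPKM and Hist1h1d at 2.54, 12.8 and 7.25 FPKM, although near-identical histone copies can share reads. Heat shock genes were lower, with a median of -0.35 (percentile 0.02), and 2 of 14 passed the size rule, Hsph1 at 47.6, 18.1 and 33.2 FPKM and Hspa8 at 1229, 536 and 945 FPKM. Hspa8 holds small RNA genes.

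Of the other lists, p53 target genes had a median of 0.21 (percentile 99.97), with the death receptor Fas, which holds a small RNA gene, at 9.96, 24.1 and 20.9 FPKM and Cdkn1a, the p21 inhibitor, at 623, 575 and 717 FPKM. NRF2 and antioxidant genes had a median of 0.18 (percentile 99.9), yet Gsr and Gclc of that list had log2 ratios of -0.61 and -0.52. The list of Mt1, Mt2 and the zinc exporter Slc30a1 (0.63 over 3 genes, percentile 99.1), extracellular matrix genes (0.14, percentile 99.4), and IGF, AKT and mTOR genes (0.13, percentile 98.3) had medians above the random range. For immediate early genes the median was 0.15 (percentile 98.8) but the mean was -0.022, with Egr3 low and Atf3, a stress-induced factor, at 4.09, 11.1 and 8.88 FPKM. Unfolded protein and integrated stress response genes (0.024), TGF-β and activin genes (-0.04), amino acid and branched-chain genes (-0.046), aryl hydrocarbon receptor targets (0.27) and ribosomal protein genes (0.12, percentile 97.2) lay inside it. In all, 22 of 34 lists stood apart, 14 higher and 8 lower, where chance would place 1.7 there. The lists share 21 genes and their members are not independent. The cholesterol and lipid list returned inside the random range at pseudocounts of 0.1 and 5, a mean FPKM of 5 or more, and with TPM, the immediate early list at a pseudocount of 5 and with TPM, the sarcomere list with TPM and without genes holding a small RNA gene, and the fibroblast list without such genes. Besides the atrophy list, aryl hydrocarbon receptor targets, ribosomal protein genes and adipocyte markers rose above the range with no filter (percentiles 99.0, 99.4 and 98.7).

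By the size rule, 235 loci were higher and 89 lower in conditioned media among 11858 with a mean of 1 FPKM or more. The authors' deposited table calls 6118 of 10982 tested loci, 2832 higher and 3286 lower. The median absolute log2 fold change of those calls in the authors' deposited table was 0.38, and 252 of them also passed the size rule. Cuffdiff's calls compare these libraries, not the conditions. The split between higher and lower depended on the pseudocount and on rescaling to TPM. It was 72.5% higher as deposited, 73.5% when centred on the median and 59.6% at a pseudocount of 5. After rescaling to TPM, which moved the median log2 ratio of all loci to 0.14, it was 83.0%. The counts of higher and lower moved to 56 and 38 at the pseudocount of 5, and to 146 and 30 after the rescaling.

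**Figure D1:**
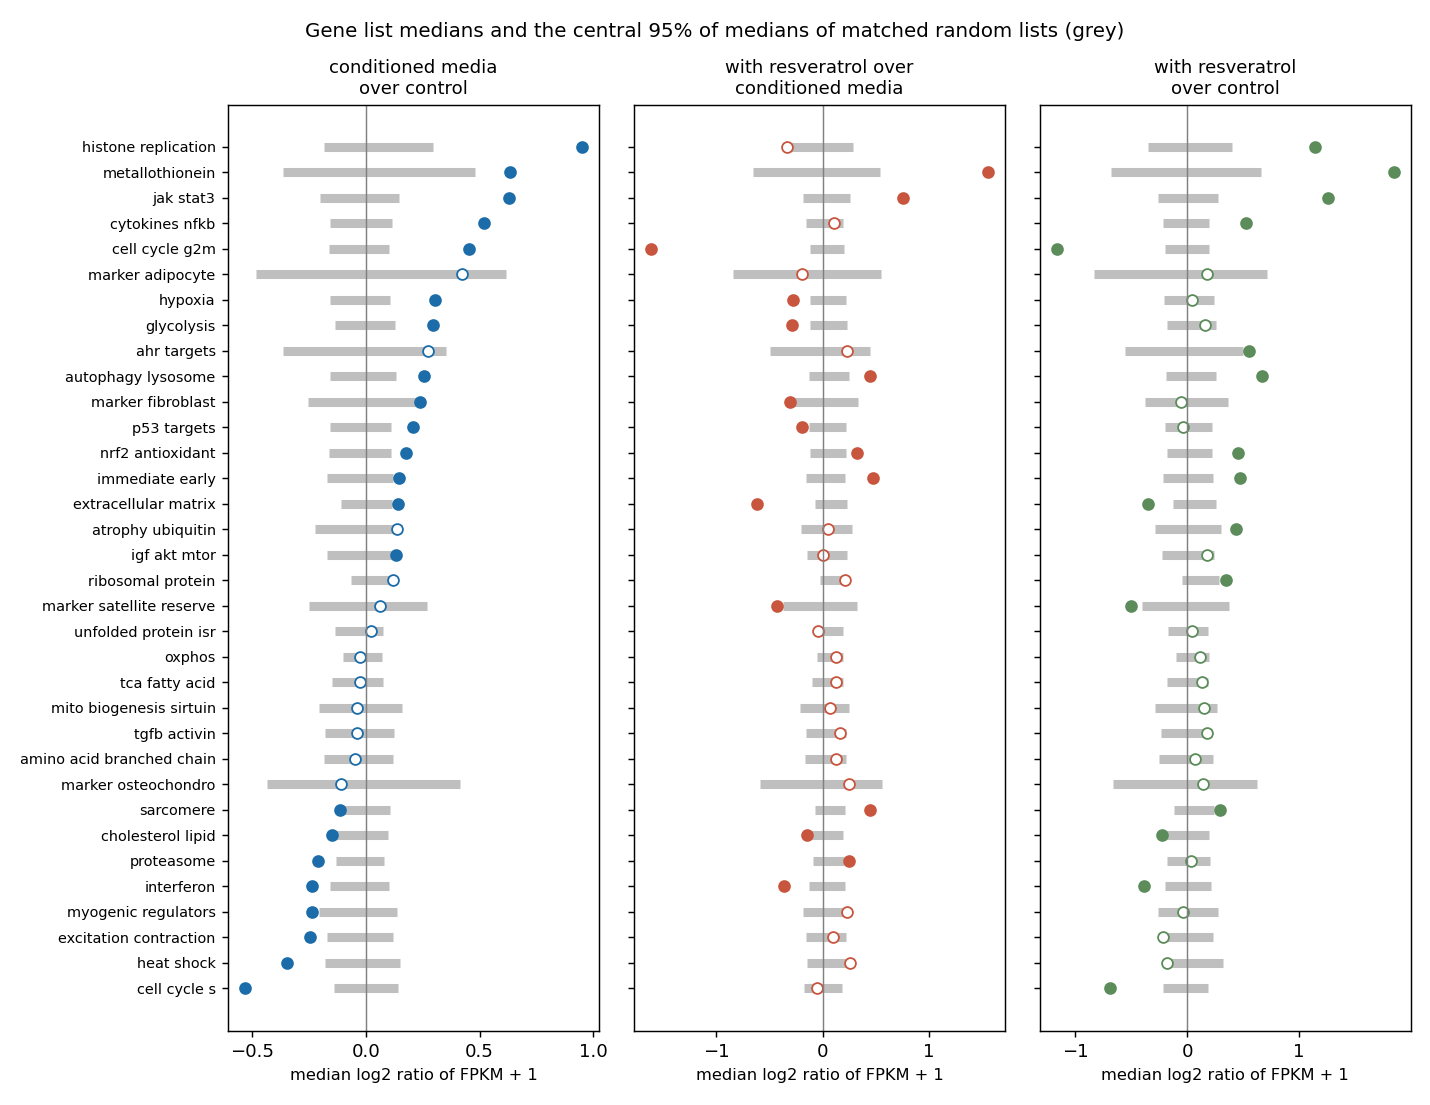
Median log2 ratio of FPKM + 1 (x axes) of each of 34 gene lists (y axis) in the 3 comparisons, with grey bars for the central 95% of medians of matched random lists and filled points for lists outside it. G2/M genes lie at 0.45 for conditioned media over control and at -1.61 for resveratrol over conditioned media.

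The second comparison asks what resveratrol changed in conditioned medium. The clearest group was the G2/M genes, all 34 of which had lower values with resveratrol. Of these, 33 passed the size rule, the median log2 ratio was -1.61, below all random lists, and the authors' deposited table calls all 34 lower. Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, stood at 43.5, 59.9 and 5.29 FPKM (log2 ratio -3.28), Plk1, polo-like kinase 1, at 12.2, 17.1 and 1.02 FPKM (log2 ratio -3.17), the checkpoint target Cdc20 at 20.98, 33.1 and 4.26 FPKM, and the cyclins Ccna2 and Ccnb1 at 39.2, 40.2 and 5.85 FPKM and 26.1, 38.7 and 5.98 FPKM. The S phase list was not set apart, with a median of -0.051 at percentile 24.6 and 1 gene past the size rule, the thymidine kinase Tk1 at 27.4, 19.2 and 5.83 FPKM. Satellite and reserve cell markers were lower together with the G2/M genes, with a median of -0.43 over 9 genes (percentile 1.32) and 7 ratios below 0, among them Myf5 at 10.9, 9.23 and 2.69 FPKM and Notch3 at 18.0, 25.7 and 12.1 FPKM. The other 2, Vcam1 at 42.6, 49.2 and 78.0 FPKM and Sdc4 at 80.6, 117 and 174 FPKM, had ratios above 0 that did not pass the size rule.

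Sarcomere genes were higher with resveratrol, while the other muscle lists lay inside the random range. Of 36 sarcomere genes, 29 had ratios above 0 and 5 passed the size rule, with a median of 0.45, above all random lists. Mybph stood at 299, 156 and 533 FPKM, the thin filament gene Lmod2 at 21.3, 16.7 and 52.3 FPKM, the perinatal myosin heavy chain Myh8 at 6.40, 7.17 and 19.9 FPKM and Tcap, telethonin, at 7.53, 11.1 and 27.8 FPKM. Ttn was at 19.97, 10.1 and 7.34 FPKM, and so did not share this. Myod1 and Myog, with the values given above, had log2 ratios of 0.85 and 0.92, while the list of myogenic regulators lay inside the random range (median 0.23, percentile 95.8), with the inhibitors Id1 and Id3 at 16.3, 13.6 and 31.6 FPKM and 14.0, 22.4 and 48.7 FPKM. Excitation-contraction genes had a median of 0.099, inside the range. For the atrophy genes the median was 0.051 (percentile 48.6), and Trim63 and Fbxo32 had log2 ratios of -0.26 and 0.061. Proteasome genes (median 0.25, percentile 99.4) and autophagy and lysosome genes (median 0.45, percentile 99.99) were higher as lists with 0 members past the size rule. Map1lc3a, an LC3 gene, was at 44.7, 56.7 and 94.6 FPKM and Atg12 at 30.2, 34.6 and 62.4 FPKM.

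JAK-STAT3 genes were higher still with resveratrol, with a median of 0.76, 5 of 16 higher by the size rule and 1 lower. Socs3 had a log2 ratio of 1.56, the transcription factor gene Cebpb stood at 14.1, 14.9 and 38.5 FPKM and Pim3 at 13.3, 13.1 and 31.8 FPKM, whereas Socs1 was at 5.39, 9.23 and 3.34 FPKM. The NF-κB and cytokine list was divided, with 4 higher, 5 lower and a median of 0.10 (percentile 80.9). Ptgs2, cyclooxygenase 2, was at 26.4, 32.6 and 113 FPKM and the chemokine Ccl5 at 27.5, 56.3 and 175 FPKM, while Icam1 and Lif were lower, Lif at 8.88, 8.20 and 2.22 FPKM. Interferon genes had a median of -0.36, below all random lists, with Oas3 at 17.7, 17.0 and 5.95 FPKM. Metallothionein genes, which bind zinc and copper, were higher, with Mt2 at 627, 973 and 3278 FPKM and Mt1 at 507, 620.1 and 1822 FPKM. NRF2 and antioxidant genes had a median of 0.32 (percentile 99.9) and 4 of 26 past the size rule, all higher: Gclc, which makes the glutathione precursor, at 10.9, 7.28 and 17.7 FPKM, the ferritin chains Ftl1 and Fth1 at 919, 1014 and 2290.5 FPKM and 915, 1061 and 2235 FPKM, and Gsta4 at 12.2, 12.2 and 27.8 FPKM. Ftl1 holds a small RNA gene. Hmox1, heme oxygenase 1, was at 44.8, 46.6 and 82.5 FPKM. Immediate early genes had a median of 0.48, with 8 higher by the size rule and 2 lower, among them Fos at 2.60, 3.18 and 11.5 FPKM and Zfp36 at 10.3, 11.9 and 39.7 FPKM.

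Glycolysis and hypoxia genes were lower with resveratrol than in conditioned media alone, with medians of -0.29 and -0.27 (percentiles 0.05 and 0.08) and 3 members of each list lower by the size rule. Pfkp and Ndrg1 were among them, and the lactate exporter Slc16a3 stood at 56.8, 76.0 and 29.9 FPKM. Ratios were below 0 for 17 of 25 glycolysis and 18 of 24 hypoxia genes. Slc16a1, at 28.2, 48.8 and 83.6 FPKM, and Slc2a1, with a log2 ratio of 0.51, went the other way. Extracellular matrix genes had a median of -0.62, below all random lists, with 25 of 28 ratios below 0 and 3 past the rule. Timp3, a metalloproteinase inhibitor, was at 164, 247 and 74.5 FPKM, Col12a1 at 159.8, 165 and 63.9 FPKM and Col1a1 at 899, 1056 and 527 FPKM. Fibroblast markers had a median of -0.30 over 8 genes (percentile 2.09). That list shares Col1a1, its only member past the size rule, with the matrix list, so the lists are not independent. Lists of p53 targets (median -0.20, percentile 0.5) and of cholesterol and lipid genes (median -0.15, percentile 1.19) were lower too. In the latter, Insig1 at 79.1, 59.6 and 168 FPKM went the other way. Of 27 p53 targets, 17 had ratios below 0 and 3 were lower by the size rule, among them Ckap2 and Gtse1. Plk3 was higher by it, at 5.11, 4.37 and 11.6 FPKM. Sirt1 passed the size rule, with a log2 ratio of 1.19, and the sirtuin and mitochondrial biogenesis list did not stand apart (median 0.073). Oxidative phosphorylation (0.13), TCA cycle and fatty acid (0.13), heat shock (0.26), unfolded protein (-0.045), TGF-β (0.16), IGF (0.0061), amino acid (0.13), ribosomal protein (0.21), histone (-0.34) and aryl hydrocarbon receptor lists (0.23) had medians inside the random range. Within several of these lists members passed the size rule. Cpt1a, the carnitine transferase of fatty acid import, stood at 31.3, 19.8 and 44.3 FPKM, Ddit3, the stress factor CHOP, at 46.6, 82.3 and 239 FPKM, the hormone gene Fgf21 at 28.0, 42.2 and 9.54 FPKM, Inhba, an activin subunit, at 39.0, 33.7 and 8.24 FPKM, Irs1, the insulin receptor substrate, at 29.4, 34.2 and 8.90 FPKM, Igf1 at 8.81, 7.65 and 2.01 FPKM, Glul, glutamine synthetase, at 20.1, 33.0 and 77.4 FPKM and Cyp1b1, a cytochrome P450, at 25.4, 30.4 and 5.34 FPKM.

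The 10 called genes highest with resveratrol over conditioned media were led by Ccl4, a chemokine, at 0.115, 0.504 and 12.6 FPKM, the antisense transcript Atcayos at 2.36, 2.39 and 21.1 FPKM, the class I gene H2-T10 at 323, 121 and 784 FPKM and the non-coding transcript Platr17 at 1.81, 2.82 and 22.3 FPKM. The span of H2-T10 is given to 8 loci, 2 of them with that symbol, and the span of Atcayos to 3, so both values are uncertain. Mmp11, Mybph, Ptgs2, Mt2, Nupr1 and Mpv17l followed, with Mmp11, a stromelysin, at 24.2, 36.4 and 139 FPKM and the stress protein gene Nupr1 at 129.8, 188 and 623 FPKM. Outside the G2/M list, the lowest genes were Nrep at 23.4, 28.0 and 2.65 FPKM, the receptor Mrgprf at 12.2, 12.2 and 0.904 FPKM, Lurap1l at 35.7, 49.6 and 6.93 FPKM, Krt14, a basal keratin, at 7.73, 14.8 and 1.62 FPKM, and Ch25h, cholesterol 25-hydroxylase, at 10.7, 19.98 and 2.58 FPKM. Size-rule counts were 182 higher and 589 lower. The authors' deposited table calls 7015 of 11033 tested loci, 3760 higher and 3255 lower, of which 687 passed the size rule. At a pseudocount of 5 the counts were 65 and 178, and after rescaling to TPM 99 and 274. Of the 34 lists, 7 stood apart higher and 9 lower. Satellite and reserve cell markers returned inside the random range at a pseudocount of 5, a mean FPKM of 5 or more and with TPM, fibroblast markers at a pseudocount of 5, with TPM and without genes holding a small RNA gene, p53 targets at a mean FPKM of 5 or more, and cholesterol and lipid genes without genes holding a small RNA gene. Lists that left the range were the histone list, lower at a pseudocount of 5 (percentile 1.04), a mean FPKM of 5 or more (1.31) and with TPM (1.81), the ribosomal protein list, higher with no filter (98.1), and the myogenic regulators, higher at a mean FPKM of 5 or more (97.6).

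**Figure D2:**
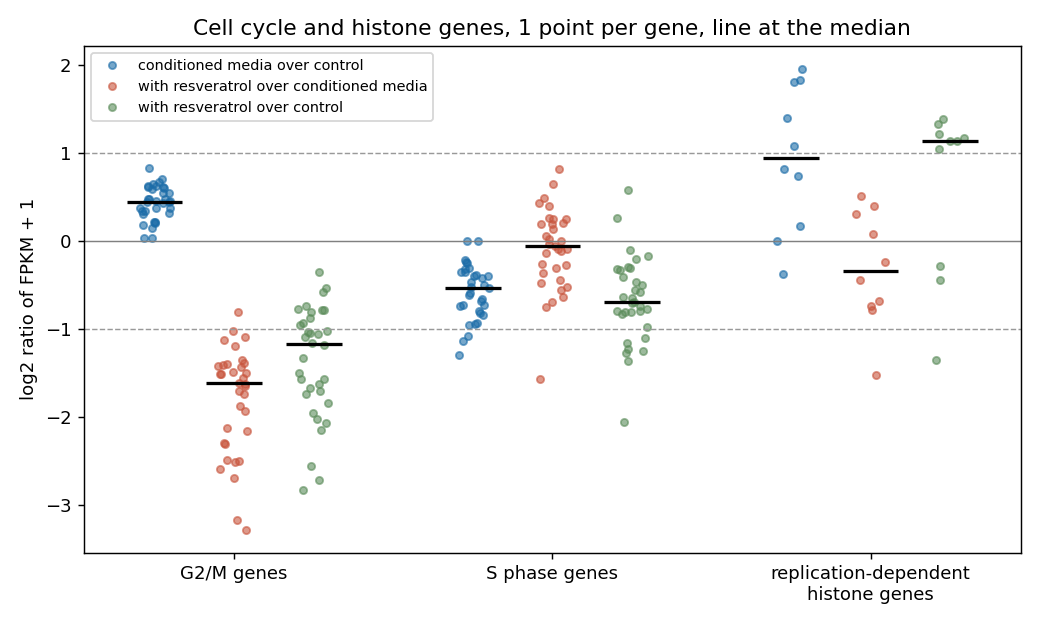
Log2 ratio of FPKM + 1 (y axis) of each measured G2/M, S phase and replication-dependent histone gene (1 point per gene, black line at the median, dashed lines at the size rule) in the 3 comparisons. The 34 G2/M genes lie above 0 for conditioned media over control and below 0 in both comparisons of the resveratrol library.

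The third comparison sets the resveratrol culture against DMEM control. Apart from the list of Mt1, Mt2 and Slc30a1, JAK-STAT3 genes had the highest list median, with 10 of 16 past the size rule and a median of 1.26. Socs3 had a log2 ratio of 2.35, Pim1 of 2.26 and Il6 of 1.54. Of 27 NF-κB and cytokine genes, 11 were higher and 1 lower, with a median of 0.53 and with Ccl5 and Cxcl1 at log2 ratios of 2.63 and 2.56. The atrophy list stood above the random range here, with a median of 0.43 (percentile 99.8) and 14 of 15 ratios above 0, though 0 passed the size rule. Trim63 and Fbxo32 had log2 ratios of 0.67 and 0.72. Autophagy and lysosome genes (median 0.66), sarcomere genes (0.30), NRF2 and antioxidant genes (0.45), Mt1, Mt2 and Slc30a1 (1.84), immediate early genes (0.47), histone genes (1.14), ribosomal protein genes (0.34) and aryl hydrocarbon receptor targets (0.55 over 5 genes, with a mean of 0.089) were higher as lists.

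On the lower side of the resveratrol over control comparison were G2/M genes, with 23 of 34 past the size rule and a median of -1.16, S phase genes, with 7 of 33 past it and a median of -0.69, interferon genes (-0.38), extracellular matrix genes (-0.35), cholesterol and lipid genes (-0.22) and satellite and reserve cell markers (-0.50). The satellite and reserve list returned inside the random range at a pseudocount of 5 and a mean FPKM of 5 or more, and the aryl hydrocarbon receptor list with no filter and at a mean of 5 or more. Glycolysis (0.16), hypoxia (0.041), p53 target (-0.038), proteasome (0.032), myogenic regulator (-0.04) and heat shock genes (-0.18) lay inside the random range. Serpina3n and Prg4 headed the higher genes, with Platr17, Mgst2, Hist1h4k, Atcayos, Ccl5, Txnip, Cxcl1 and Hist1h4j. Txnip, an inhibitor of thioredoxin and of glucose uptake, stood at 48.4, 168 and 299 FPKM (log2 ratio 2.60). Fam65a was lowest, followed by the chemerin receptor Cmklr1 at 20.4, 7.47 and 1.12 FPKM, the matricellular gene Wisp1 at 178, 92.3 and 19.5 FPKM, Apol10b at 28.7, 12.4 and 2.56 FPKM, Dynap, Ube2c, Mrgprf, Nrep, Gper1 and Plk1. In this comparison 427 loci were higher and 622 lower by the size rule, so that 40.7% were higher. After rescaling to TPM these were 354 and 219, with 61.8% higher, so the direction in which more loci lay depended on whether FPKM were rescaled. The authors' deposited table calls 7458 of 10939 loci, 3729 in each direction, of which 933 passed the size rule.

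**Figure D3:**
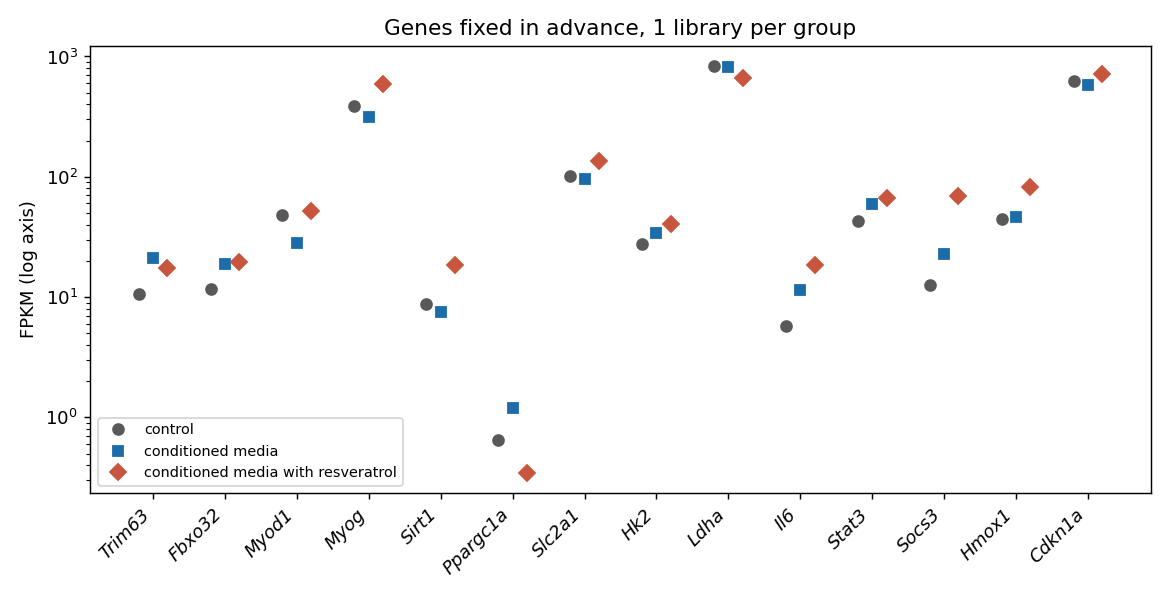
FPKM (y axis, log scale) of 14 genes fixed before the data were examined, in the control, conditioned media and resveratrol libraries (1 library per group, no error bars). Socs3 stands at 12.7, 22.7 and 68.8 FPKM, and Sirt1 at 8.72, 7.48 and 18.4 FPKM. Mstn, listed at 0 in control, is not drawn.

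Conditioned media and resveratrol could also be set side by side gene by gene. Of the 235 loci higher in conditioned media, 175 (74.5%) had ratios of the opposite sign with resveratrol, 68 of them past the size rule, and 91 were still past it against control. Of the 89 lower, 38 (42.7%) had ratios of the opposite sign, 8 past the rule, and 56 were still past it. Lists of these sizes drawn independently would share 11.7 and 1.37 loci where 68 and 8 were shared. Past the size rule in the same direction again with resveratrol were 6 of the loci higher in conditioned media and 9 of those lower, where independent lists would share 3.61 and 4.42. Both comparisons use the same conditioned media library, so its chance deviations alone make them run opposite ways. Over 10640 loci tested by the authors throughout, the correlation across genes, which are not independent replicates, was -0.18. In simulated unchanged libraries it was -0.46 on average (central 95% -0.67 to -0.23), so the observed correlation was less negative than that range. The covariance was -0.0352, against a simulated mean of -0.0375 (central 95% -0.0829 to -0.0192). Over these loci it thus did not exceed what the shared library gives as simulated. They held 23 of the 68 loci higher and then lower past the rule, and 7 of the 8 lower and then higher. Most of those 68 were left out, so the covariance does not speak for them. In that subset, 212 loci passed the size rule in conditioned media over control, of which 127 (59.9%) had opposite signs with resveratrol and 85 the same sign, against means of 83.3, 67.0 (80.5%) and 16.3 in the simulation. Loci of both kinds were thus more numerous than in unchanged libraries, and the share with opposite signs was smaller.

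Endothelial, macrophage, epithelial and adipocyte markers were low, while the fibroblast list held abundant genes and Spp1 alone was abundant on the osteochondral list. Endothelial genes did not reach 1 FPKM in any library (highest Vwf at 0.458). Macrophage genes reached at most 6.53 FPKM (Cd14), with Ptprc and Adgre1 listed at 0, and epithelial genes 2.74 FPKM (Krt19). Lists with fewer than 3 measured genes, which were these 3, were not placed among random lists. The 3 measured adipocyte markers had a median of 0.42 for conditioned media over control, inside the random range, with Lpl at most 7.47 FPKM. Of 10 osteochondral markers, the 3 with a mean of 1 FPKM or more had a median of -0.11. They were Spp1, osteopontin, at 1468, 1528 and 3097 FPKM, Runx2 at 13.3, 11.8 and 8.12 FPKM and Sox9 at 11.6, 10.7 and 12.9 FPKM. Fibroblast markers, with Col1a1 at the values given above, had a median of 0.24 (percentile 98.1) for conditioned media over control and -0.059 for resveratrol over control. Satellite and reserve cell markers had a median of 0.063 for conditioned media over control.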

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

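Every setting was run on single libraries, so no result has a replicate to leave out, and no paired analysis was possible because each group holds 1 library. The alternatives without small RNA genes or with 1 symbol only, and TPM for lists and genes, were chosen after seeing the data. Counts by the size rule depended on the pseudocount. In conditioned media over control, 235 higher and 89 lower became 450 and 149 at a pseudocount of 0.1 and 56 and 38 at 5, the higher count became 120 at a mean FPKM of 5 or more, and both became 146 and 30 with TPM. For resveratrol over conditioned media, 182 and 589 became 299 and 884 at 0.1, 65 and 178 at 5 and 99 and 274 with TPM, and the lower count became 359 at a mean FPKM of 5 or more. For resveratrol over control, 427 and 622 became 161 and 229 at a pseudocount of 5, the higher count became 283 at a mean FPKM of 5 or more, and the lower count became 219 with TPM. A larger pseudocount or filter removes low genes by construction, and TPM divides values by about 3, which acts like a larger pseudocount, besides the shift. Joined with the size rule, the authors' calls in the deposited table became 252, 687 and 933. The share of conditioned media loci with opposite sign under resveratrol, which the shared library raises by itself, was 65.7%, and became 57.4% at a pseudocount of 5 and 58.5% at a mean FPKM of 5 or more. The cause was not tested. Other counts stayed within 1.5 times under the other settings. Of 705 list values under alternatives, 675 kept their place inside, above or below the random range, which centring keeps by construction, 19 returned inside it, 9 left it, and 2 of lists that stood apart turned sign: the sarcomere median of conditioned media over control became 0.075 and the cholesterol and lipid median 0.045 with TPM, both inside the range. Lists inside the range in the main setting turned sign in 21 of 323 values, 10 of them with TPM, and their signs are not firm. Among those that left were the atrophy list in conditioned media over control at a mean FPKM of 5 or more, and the histone list in resveratrol over conditioned media at a pseudocount of 5, a mean FPKM of 5 or more and with TPM. Among lists that returned inside were cholesterol and lipid genes in conditioned media over control at pseudocounts of 0.1 and 5, satellite and reserve markers at a pseudocount of 5 and a mean FPKM of 5 or more, and fibroblast markers without small RNA genes. Of 2760 values of named genes, 420 moved by more than the standard error that the authors' test implies. Where the test implies none, any change counted as a move. Settings of the filter on mean FPKM leave a gene's value unchanged by construction. Of the values past the size rule 0 changed sign, which was fixed in advance. A pseudocount keeps the sign, and centring and TPM shift ratios by far less than 1. With depth unknown, the precision of low genes rests on the standard errors that the authors' test implies for their log2 fold changes. These were 1.64 for Icam1 in conditioned media over control and 0.50 for Plk1 with resveratrol over conditioned media. No replicate culture stands behind them.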

Other observations

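The tests on G2/M genes, those on small RNA loci and S phase genes for the histones, and those on matrix, glycolysis and hypoxia genes against control, were chosen after the result was seen. Ribosome assembly genes formed a group that the fixed lists did not hold. It was noticed that Srm and several nucleolar genes were lower in conditioned media, and 47 ribosome assembly genes that had not been looked at were then listed. Of 46 measured, 45 had ratios below 0 for conditioned media over control, and their median of -0.50 lay below the central 95% of random lists (-0.15 to 0.071). This list was not run under the alternative settings, among them the one without genes that hold a small RNA gene. Dkc1, which modifies ribosomal RNA, stood at 21.1, 9.53 and 8.18 FPKM in control, conditioned media and resveratrol, and Nop2, a ribosomal RNA methyltransferase, at 27.8, 14.0 and 16.5 FPKM. For resveratrol over conditioned media their median was 0.059 (percentile 52.4), and over control -0.46, so the lower level was also present with resveratrol. Both comparisons against control use the same control library, and that library alone being out of place would give this too. Ribosomal protein genes did not share the fall, with 32 of 34 ratios above 0 for conditioned media over control and a median of 0.12 inside the random range.

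Smooth muscle and actin cytoskeleton genes were lower as well, a hypothesis taken from Myl9, Actg2 and Cnn1 and tested on 25 other genes. Their median for conditioned media over control was -0.34, below the random range (-0.12 to 0.12), with 20 of 25 ratios below 0. Acta2, smooth muscle alpha actin, stood at 892, 468 and 637 FPKM and Tagln, transgelin, at 218, 103 and 109.9 FPKM. With resveratrol the median was lower again, at -0.30 over conditioned media and -0.73 over control, with 7 of 25 past the size rule in the latter. Over conditioned media 18 of 25 ratios were below 0, 4 of them past the size rule, and 7 were above 0. Acta2 and Tagln were among the 7, at log2 ratios of 0.44 and 0.091, so they did not share the second fall. This list was not run under the alternative settings. Both groups may be responses of these cultures to the medium, but 1 library per group leaves a difference between cultures unrelated to the medium open. The serum content of the media is not given in the sources used here, so these and the other differences of conditioned media over control, S phase genes included, may reflect serum or used-up nutrients rather than factors from the cancer cells.

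Had the conditioned media library alone been out of place, the G2/M genes that were lower with resveratrol would lie level with control, but their median over control was -1.16, below the random range of -0.19 to 0.19. One scaling factor would move random lists matched on expression as far, but the G2/M median of -1.613 for resveratrol over conditioned media lay below their range of -0.12 to 0.20. These are the values that set the list apart at first, so this is no separate test. An equal loss of all cycling cells would lower S phase genes alike if only cycling cells expressed them, which was not tested. The S phase median lay above the G2/M median by 1.56, more than the 0.56 interquartile range of S phase genes. S phase genes thus did not fall with the G2/M genes there. Against control both lists were lower and the gap was 0.478, within the interquartile range of 0.499. That range is a spread of genes and not an error of the gap, so an equal loss stays open. An effect of resveratrol, which the design names, stays open as untested, and so does a resveratrol culture that held fewer mitotic or unfused cells by chance. Satellite and reserve cell markers were lower too, with a median of -0.43 over 9 genes, but Sdc4 and Vcam1 had ratios above 0, short of the size rule. The list returned inside the random range at a pseudocount of 5, a mean FPKM of 5 or more and with TPM. No table here measures unfused cells or passage through mitosis. A culture with resveratrol in control medium was not analysed here, so an effect of resveratrol cannot be separated from one that needs conditioned medium.

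Histone genes were higher in both conditioned media libraries, with 29 of 30 histone loci above 0 for conditioned media over control and a median of 1.05. If more non-polyadenylated RNA had been kept, small RNA loci might be higher too, and 84 of them had a median of -0.39. Loci without a symbol need not be small RNA, and small RNA need not follow longer non-polyadenylated RNA such as histone transcripts, so this cannot decide. More cells in S phase would raise S phase genes, whose median was -0.53. Reads moved between near-identical copies would leave the sum of histone loci level, but it went from 239.7 to 704 FPKM, a log2 ratio of 1.55. Polyadenylated histone transcripts, which differentiated cells make, are a possible explanation that FPKM per locus cannot test, and a difference in library preparation between single libraries stays open.

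For resveratrol over conditioned media the median of the 30 histone loci was 0.40 while that of the 10 genes on the fixed list was -0.34, so the direction depended on which histone genes were taken.

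The opposite signs of conditioned media and resveratrol ratios may come from the library that both comparisons share. Across the loci tested throughout the covariance was -0.0352, inside the -0.0829 to -0.0192 of simulated unchanged libraries, and without the G2/M genes it was -0.0327. The 68 loci past the size rule higher in conditioned media and lower with resveratrol exceeded the 11.7 of independent lists, but that figure leaves out the shared library. Simulated unchanged libraries, which include it, gave on average 12.6 such loci (central 95% 6 to 19) where 23 were observed among the loci tested throughout, 10.3 loci lower and then higher (5 to 17) where 7 were observed, and 67.0 loci past the rule with opposite signs (53 to 81) where 127 were observed. Loci with the same sign were also more numerous, at 85 against 16.3. The loci tested throughout left out most of the 68, so the simulation does not speak for those. Over the loci it covers, the shared library as simulated thus gives the covariance, a more negative correlation, and fewer loci with opposite signs. It is unknown how far the errors behind the simulated noise already hold differences among these libraries. If they do, a covariance inside the simulated range is partly built in. How many of the loci with opposite signs a change by resveratrol accounts for stays open. Glycolysis and hypoxia genes, whose lists were higher in conditioned media and lower with resveratrol, belong to this open case, since their medians over control, 0.16 and 0.041, lay inside the random range. For matrix genes the shared library alone would leave the resveratrol library level with control, but their median there was -0.35, below the random range of -0.13 to 0.26. Their smaller rise in conditioned media, with a median of 0.14, stays open.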
